A study of Mus musculus with 8 samples.

How the data were processed

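The labels describe RNA-seq of small intestine adenomas from C57BL/6 background mice, 4 ApcMin/+ and 4 ApcMin/+ with both copies of Sfn deleted, with 1 adenoma library per mouse. Total RNA was made into strand-specific Illumina libraries, per the labels' protocols. The authors deposited a single sheet of normalised read counts with 48440 gene rows, treated here as a score rather than as counts because, per the file headers, it holds values after RUVs, a method that estimates unwanted factors from differences among replicates and subtracts them. The values are whole numbers and the upper quartile is nearly the same in all libraries, 152 to 157. The genome build is mm10, per the submitters' processing notes, while the aligner, the counting method, the gene annotation and the settings of RUVs are not given in the sources used here. The raw depth of each library is therefore unknown, and no counting interval is given.

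Libraries were assigned to genotypes by mouse number and genotype in the labels. A knockout column carries a mouse number that the labels give to an ApcMin/+ mouse, so it was assigned to the knockout group without a replicate number and is called the unnumbered knockout library. The number of columns of other samples was 0. ApcMin/+ replicates 1 and 2 and all knockout libraries share a sequencing order, and ApcMin/+ replicates 3 and 4 come from another. The mice are separate animals, so the spread between libraries is biological as well as technical. Left out were 27 rows whose gene names had been turned into dates by spreadsheet software.

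Subtraction of factors estimated among replicates leaves fewer independent deviations between replicates than the number of libraries implies, which makes p-values too small. The singular values of deviations from the genotype means were computed on 12052 genes with all values at 100 or above. They were 53.8, 32.0, 28.3, 23.3, 18.9 and 0.0954, so 1 of 6 directions had been removed. It sets ApcMin/+ replicates 1 and 2 against ApcMin/+ replicates 3 and 4, that is, it contrasts the sequencing orders. Fold changes within the shared order are therefore close to those over all libraries by construction, and cannot show whether sequencing order matters. By a rule fixed before the data were examined, a direction under 0.1 of the largest entered the model as a covariate, which leaves fold changes as they are and gives 5 residual degrees of freedom. Where a library or a sequencing order was left out, the rule was applied again to the remaining libraries.

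Genes with a value of at least 10 in at least 4 libraries were tested, 17523 in all, with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend) on log2(value + 1). P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, knockout minus ApcMin/+, which understates changes of low genes. The targeted gene was tested by a two-sided exact permutation of the group labels. Gene lists for cell types, pathways and other tissues, 50 with at least 5 tested members, were written before the data were examined and tested with limma camera at an inter-gene correlation of 0.01. Estimated correlation, ranks and fry served as alternatives, the last added afterwards. List means per library were also compared by exact permutation, added afterwards. A permutation assumes exchangeable libraries, which normalisation among replicates does not leave, so its p-values can be too small. Gene positions came from GENCODE release M21 on GRCm38, the assembly also called mm10, with 46213 rows matched by symbol and 581 by synonym. Genes starting within 10 Mb of Sfn were compared with all others by Fisher's exact test, two-sided. Pseudogenes were matched to the coding gene that shares most of their 31-base words in the GENCODE transcripts, a step added after the data were seen.

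Genes named in the text were chosen by a rule fixed before the data were examined. It takes all 14-3-3 genes, and the 10 largest rises and 10 largest falls among genes that passed, with a mean log2 value of at least 5 and no overlap between the genotypes, without symbols of predicted genes. It also takes 4 members of each list called by camera, with the smallest p in the direction of the list, and 2 members of other lists described. Genes near Sfn outside this rule, gene and pseudogene pairs and further mast cell and neutrophil genes were chosen after their values were seen.

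Alternatives were pseudocounts of 0.5 and 5, no filter or a filter of 50, median-ratio scaling, quantile normalisation, genotype without the removed direction, sequencing order as a covariate, the 6 libraries of the shared order, array weights, robust eBayes and leaving out each library. Added after the data were seen were Xist-high libraries as a covariate, the 5 Xist-low libraries alone and a threshold of 0.1. The model was tested on simulated data for this comparison with 17204 genes, the removed direction included. It found the 1 removed direction and recovered 63% of 100 genes changed 2-fold and 86% of 100 genes changed 4-fold, with 6.29% of calls being unchanged genes. Without the covariate the share of unchanged genes among the calls was 16.8%. Camera called a list shifted by a known amount and 0 of 49 unshifted lists. The simulated genes varied independently of each other, so this outcome cannot show how camera behaves with correlated genes. Plots were drawn with matplotlib 3.10.9.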

Results

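RNA was measured in small intestinal adenomas of ApcMin/+ mice, which carry a truncating allele of the tumour suppressor gene Apc and form intestinal polyps. The adenomas came from 4 mice with intact 14-3-3σ and from 4 mice that lacked 14-3-3σ, the protein of the gene Sfn, which binds phosphorylated proteins and is induced by p53 after DNA damage. The comparison asked how loss of 14-3-3σ changes the transcriptome of these tumours. The ApcMin/+ mice were 256 to 282 days old and the knockout mice 144 to 148 days old, so age and genotype could not be separated. The normalised read counts summed to between 34182800 and 46707800 per library, and sequencing depth before normalisation is unknown. Xist, the RNA of the inactive X chromosome, was above 1000 in ApcMin/+ replicates 2 and 3 and in 1 knockout library, and the Y-linked gene Ddx3y lay at 2 or below in these 3 libraries and at 1435 or above in the other 5.

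Sfn (chromosome 4, 133600556 to 133602168, GRCm38) was high in every ApcMin/+ adenoma and close to 0 in every knockout adenoma. Its normalised read count was 14607, 6585, 6989 and 15968 in ApcMin/+ replicates 1 to 4, a mean of 11037 ± 4942 (SD, n = 4). The 4 knockout libraries were at 1, 0, 0 and 1, a mean of 0.5 ± 0.577 (SD, n = 4). The difference of -12.81 on the log2(value + 1) scale had a two-sided exact permutation p of 0.0286 over 70 arrangements, the smallest p that 4 against 4 libraries allow. The size of this difference depends on the pseudocount because the knockout libraries are at the floor. Within the 6 libraries of the shared sequencing order, 2 ApcMin/+ and 4 knockout, it was -12.76 with an exact permutation p of 0.0667, the smallest that 6 libraries allow. The 6 other 14-3-3 genes differed by -0.15 (Ywhae) to 0.10 (Ywhaq) on the log2 scale, and none passed the limma threshold. The sign for Ywhaz turned under median-ratio and quantile scaling and that for Ywhag under quantile scaling.

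**Figure D1:**
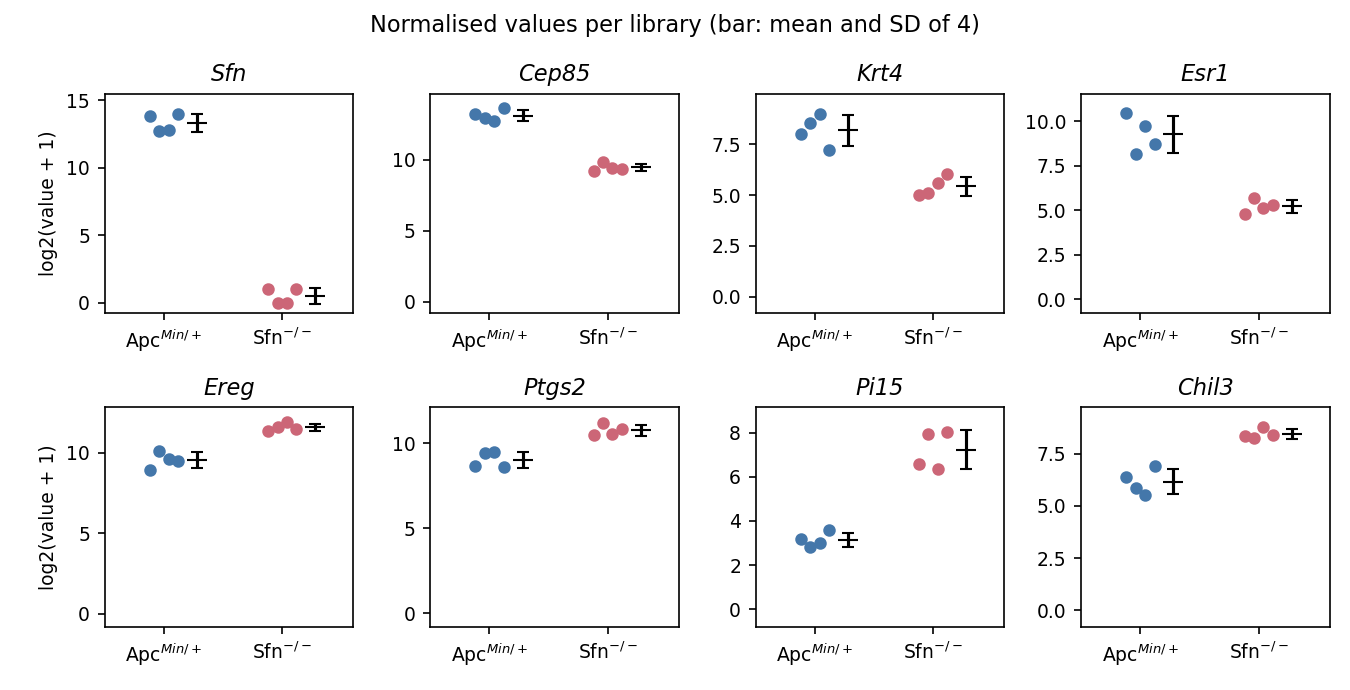
Normalised values of 8 genes in each library, on a log2(value + 1) axis, with ApcMin/+ adenomas in blue, ApcMin/+ Sfn-/- adenomas in red and bars for the mean and SD of 4 libraries. Sfn lies at 0 or 1 in the knockout libraries. In each panel the 4 libraries of a genotype do not overlap those of the other, which the rule that chose these genes required.

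Of 17523 genes tested, 58 differed between the genotypes at a limma adjusted p under 0.05, 33 higher and 25 lower in the knockout adenomas. Ptgs2 and Ereg were among the genes that rose. Ptgs2, which encodes the inducible cyclooxygenase COX-2, went from 548 ± 172 to 1795 ± 433 (SD, n = 4 each; log2 fold change 1.73, limma adjusted p = 0.0396). Ereg, which encodes the EGF receptor ligand epiregulin, went from 768 ± 262 to 3065 ± 502 (log2 fold change 2.04, adjusted p = 0.0167). Chil3, a chitinase-like protein of myeloid cells, rose by 2.28, and Pi15, a peptidase inhibitor, rose from 8.0 to 168.5, a log2 fold change of 4.07 (limma adjusted p 0.0294 and 0.0109). The lymphatic marker Lyve1 rose by 1.19 and the BMP antagonist Grem1 by 1.04 (limma adjusted p 0.0497 and 0.0478). Of 21 alternative settings, Lyve1 lost its call in 13, Grem1 in 10, Ptgs2 in 8, Ereg and Chil3 in 6 each and Pi15 in 2, with the direction kept. Among the genes that fell, the estrogen receptor gene Esr1 went from 746 ± 516 to 37.5 ± 10.1 (log2 fold change -4.04, adjusted p = 0.0174). The squamous keratin gene Krt4 went from 316 ± 153.4 to 43.8 ± 15.3 (-2.74, adjusted p = 0.0426). Krt4 lost its call in 9 of the 21 settings and Esr1 in 5. Chd9, a chromodomain helicase, fell by 1.68 and the carboxylesterase gene Ces1f fell from 1429 ± 1419 to 1.75 ± 1.26, close to the floor (limma adjusted p 0.00688 and 0.00906). Abhd1 rose by 3.41, while RP23-359B23.11, which has no position in the annotation, fell by 3.09 (limma adjusted p 0.00688 and 0.0360). RP23-359B23.11 lost its call in 6 settings, Abhd1 in 2, and Chd9 and Ces1f in 1 each.

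Of the 58 genes, 48 changed over 2-fold, 28 higher and 20 lower. The libraries of the genotypes did not overlap for any of the 58, nor for 2816 of all tested genes (16.1%). Chance gives 2.86% among exchangeable libraries, but the normalisation removed differences between replicates, so these libraries are not exchangeable. The split of 33 higher and 25 lower was 38 and 18 after median-ratio scaling and 40 and 20 after quantile normalisation. The number of genes depended on the libraries and on the model: it was 18 with sequencing order as a covariate, 16 within the shared order, 13 with array weights and 426 when the direction that normalisation had removed was not counted. In the 5 libraries with low Xist it was 2194, 713 higher and 1481 lower, so the lean towards higher genes turned. Without ApcMin/+ replicate 2 it was 346, without ApcMin/+ replicate 4 it was 144, and without knockout replicates 2, 3 and 4 and the unnumbered knockout library it was 33, 21, 25 and 25. All 58 genes kept their direction in each of these fits.

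The genes that changed were concentrated on the chromosome that carries Sfn. Within 10 Mb of Sfn, 9 of 313 tested genes passed (2.88%), against 48 of 16977 elsewhere (0.283%), an odds ratio of 10.4 (95% interval 4.46 to 21.8; Fisher's exact test, two-sided p = 7.81e-07). Besides Sfn, 6 of them fell and 2 rose. Cep85, a centrosomal protein gene 0.529 Mb from Sfn (134129858 to 134187112), went from 9074 ± 2644 to 712 ± 137 (SD, n = 4 each; log2 fold change -3.64, limma adjusted p = 0.000310). The neighbouring genes Hmgn2, a nucleosome-binding protein gene (133964738 to 133968650), and Sh3bgrl3 (134127406 to 134128789) fell by 1.64 and 1.24 (limma adjusted p 0.00539 and 0.0294). Col16a1, a fibril-associated collagen gene (130047840 to 130099283), rose by 2.48 and the zinc transporter gene Slc30a2 by 1.68 (adjusted p 0.00688 for each). Hdac1, Serinc2 and Ndufs5 fell by 1.13, 0.97 and 1.10 (limma adjusted p 0.00648, 0.0294 and 0.0406). Of 21 alternative settings, Serinc2, Ndufs5 and Sh3bgrl3 lost their call in 7 each, Col16a1 in 2, Hdac1 and Slc30a2 in 1 each, and Cep85 and Hmgn2 in 0. Slc30a2, Hdac1, Serinc2 and Ndufs5 are named because they lie in this window and were chosen after their values were seen. Within the shared sequencing order the odds ratio was 25.01 with 5 genes (Fisher's exact p = 6.98e-06). It was 2.84 with 20 genes when the removed direction was not counted, and 1.43 with 53 genes in the 5 libraries with low Xist. It was 3.14 without ApcMin/+ replicate 2 and 5.25 without ApcMin/+ replicate 4, and 12.3, 23.7, 17.4 and 18.4 without knockout replicates 2, 3 and 4 and the unnumbered knockout library. By chromosome, 17 of 1062 genes on chromosome 4 and 10 of 900 on chromosome 3 passed, the 2 chromosomes with an excess (Fisher's exact test, adjusted p 6.57e-07 and 0.0071).

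**Figure D2:**
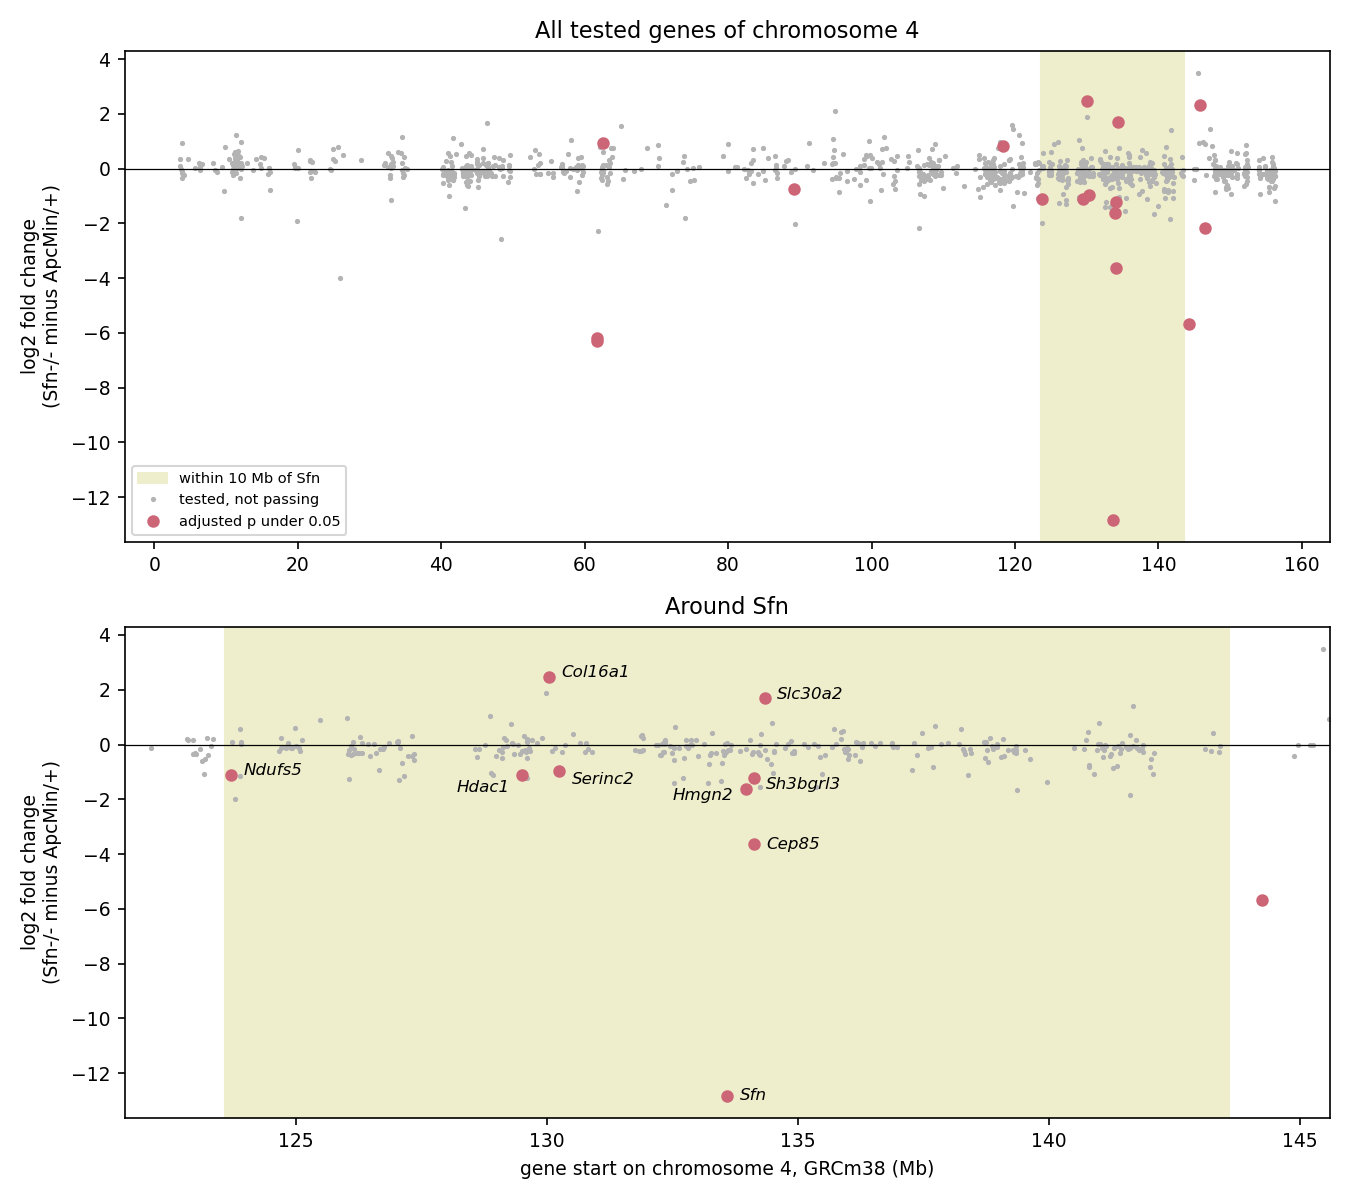
Log2 fold change of each tested gene of chromosome 4 against its start (GRCm38, Mb), for the whole chromosome and around Sfn, with genes that passed limma in red and a band of 10 Mb on each side of Sfn shaded. The 9 red points inside the band are Sfn, 6 genes that fell and 2 that rose.

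In 4 pairs of changed genes, a coding gene and the pseudogene that matches it moved in opposite directions. Rps3a1, a ribosomal protein gene on chromosome 3 (86137940 to 86142702), fell from 42314 to 10720 while its pseudogene Rps3a3 on chromosome 13 (108670603 to 108671397) rose from 44.2 to 16781 (limma adjusted p 0.0473 and 2.00e-06), and they share 67.2% of the 31-base words of the pseudogene. In knockout replicate 4 Rps3a1 was at 19939 and Rps3a3 at 10666. The other knockout libraries lay between 6632 and 9116 for Rps3a1 and between 16690 and 21882 for Rps3a3. A further pseudogene matched to Rps3a1, Gm5586, fell by 2.20 along with it (adjusted p = 0.0271 in limma). Hdac1 fell from 6152 to 2816 while Gm10093, which shares 86.1% of its 31-base words with Hdac1, rose from 17.5 to 2111. Ndufs5 fell from 1952 to 901 while BC002163 (81.0% shared) rose from 4.0 to 522.5. Psma3, a proteasome subunit gene, rose from 3140 to 4693 while Gm4742 (34.7% shared) fell from 73.5 to 2.25. The sum of gene and pseudogene differed by -0.63 for Rps3a1, -0.32 for Hdac1 and 0.55 for Psma3 on the log2 scale (exact permutation p = 0.0286 for each) and by -0.45 for Ndufs5 (exact permutation p = 0.0571). Annotated pseudogenes made up 14 of the 57 changed genes with an annotated type (24.6%), against 4.84% of the other tested genes (odds ratio 6.40, Fisher's exact p = 4.49e-07). BC021767 and Znf41-ps, 2 further pseudogenes, rose by 2.63 and 2.33 (limma adjusted p 0.0294 and 0.0372). Calls were lost for Psma3 in 13 of 21 alternative settings, Rps3a1 in 11, Znf41-ps in 9, Gm10093, Gm5586 and Ndufs5 in 7 each, BC021767 in 6 and BC002163 in 1. Gene and copy share sequence, so the value of each alone is uncertain.

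Tuft cell markers were lower in the knockout adenomas. Tuft cells are chemosensory epithelial cells of the intestine. Of 21 measured markers, 14 fell with p adjusted over the list alone and 0 rose, with a median log2 fold change of -0.99 (limma camera adjusted p = 4.74e-09; 0.66 with an estimated correlation). Over all genes tested, 0 of the 21 passed, and 20 of 21 lay below 0. Sh2d7 fell from 174.5 ± 58.1 to 48.0 ± 5.48 (SD, n = 4 each; log2 fold change -1.78, limma adjusted p over the list alone 0.00197). Fyb fell by 0.89 and Lrmp from a mean of 397.5 to 137 (limma, adjusted over the list alone, 0.00221 and 0.00319). The mean log2 level of the list lay between 8.30 and 8.99 in the ApcMin/+ libraries and between 7.63 and 7.78 in the knockout libraries (exact permutation p = 0.0286, adjusted 0.159 over 50 lists). This list and the p53 list passed limma fry in a common direction (adjusted p = 0.0488 for each).

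Type I interferon response genes were lower as well. Of 30 measured members, 14 fell with p adjusted over the list alone and 0 rose, 0 passed over all genes, and the median log2 fold change was -0.77 (camera adjusted p = 2.35e-08 in limma; 0.74 with an estimated correlation). Oas2, an antiviral sensor of double-stranded RNA, fell from 209 ± 96.4 to 46.8 ± 26.7 (SD, n = 4 each; log2 fold change -2.22), Usp18 fell by 1.27, Dhx58 fell from 425.5 to 218 and Bst2 fell by 0.76 (adjusted over the list alone, 0.0176 for each of the 4 in limma). Of 35 p53 target genes, 5 fell adjusted over the list alone, 0 rose and 0 passed over all genes, with a median of -0.18 (limma camera adjusted p = 0.0111; 0.66 with an estimated correlation). Ccng1 fell by 0.30, Phlda3 by 0.68, Dcxr by 0.58 and Ddit4l by 0.80 (adjusted over the list alone, 0.0461, 0.0399, 0.0383 and 0.0399). The call of p53 target genes was lost in the 5 libraries with low Xist (-0.20, adjusted p = 0.178). For both lists the means of the 4 knockout libraries lay below those of the 4 ApcMin/+ libraries (exact permutation p = 0.0286, adjusted 0.159). The normalised libraries are not exchangeable, so that p can be too small.

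Fibroblast and matrix genes were higher in the knockout adenomas. Of 28 fibroblast and extracellular matrix genes, 17 rose adjusted over the list alone, 0 fell and 0 passed over all genes, with a median log2 fold change of 0.58 (limma camera adjusted p = 1.37e-10; 0.66 with an estimated correlation). Fbn1, which encodes fibrillin, rose from 713.5 ± 53.6 to 1286 ± 207 (SD, n = 4 each; log2 fold change 0.84), and Col5a1, Col5a2 and Sfrp1 rose by 0.92, 0.93 and 1.05. Of 31 genes of epithelial-mesenchymal transition, 8 rose adjusted over the list alone, 0 fell and 0 passed over all genes, with a median of 0.60 (limma camera adjusted p = 5.55e-11; 0.66 with an estimated correlation). They included the collagen cross-linking enzyme gene Lox (1.35), Col3a1 (0.87) and the matrix glycoprotein gene Tnc (0.76), all of them matrix genes that fibroblasts also express, and the lists share 3 measured genes. For each of both lists the 4 knockout libraries lay above the 4 ApcMin/+ libraries (exact permutation p = 0.0286, adjusted 0.159). In the 5 libraries with low Xist the median was larger, 0.91 for the fibroblast list and 0.98 for the transition list. Of 21 endothelial genes, Lyve1 rose, adjusted over the list alone and over all genes, and 20 did not pass, Kdr (0.35), Flt4 (0.55) and Tek (0.68) among them. The endothelial median was 0.24 (limma camera adjusted p = 0.000581; 0.74 with an estimated correlation). Smooth muscle genes, another stromal list, had a median of -0.20 with 15 of 20 members below 0 (limma camera adjusted p = 0.82).

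TNF and NF-kB response, STAT3 target and senescence-associated genes were called higher by camera too. Members of the STAT3 and senescence lists moved both ways. Of 25 TNF and NF-kB response genes, 8 rose adjusted over the list alone, 0 fell and Ptgs2 passed over all genes, with a median of 0.15 and a mean of 0.42 (limma camera adjusted p = 0.00102; 0.74 with an estimated correlation). The cytokine gene Il6 went from 31 ± 6.22 to 182.5 ± 100.1 (SD, n = 4 each; log2 fold change 2.33), and the neutrophil-attracting chemokine genes Cxcl1 and Cxcl2 rose by 1.47 and 1.59 (adjusted over the list alone, 0.00963, 0.0160 and 0.0181 in limma). Of 29 STAT3 target and acute epithelial response genes, 6 rose and 4 fell adjusted over the list alone, and 0 passed over all genes (median 0.21, limma camera adjusted p = 0.00415; 0.74 with an estimated correlation). Il11 rose by 1.23, Hif1a by 0.67 and S100a8, a calcium-binding protein gene of neutrophils, by 2.81. The 4 that fell were Duox2, Duoxa2, Fut2 and Bcl2l1, at -0.95, -0.99, -0.43 and -0.34. The call of STAT3 target and acute epithelial response genes was lost in the 5 libraries with low Xist (0.18, adjusted p = 0.0767). Of 19 senescence-associated genes, 6 rose and 2 fell adjusted over the list alone and 0 passed over all genes. Their median was 0.21 (limma camera adjusted p = 0.00746; 0.81 with an estimated correlation). Il6 is on all 3 of these lists, and S100a8 is also on the neutrophil and mast cell list. Igfbp5, Mmp13 and Igfbp3 rose by 0.93, 1.02 and 0.59. The senescence call was lost without knockout replicate 2 (adjusted p = 0.0755) and with array weights (0.157). Library means of the genotypes overlapped for the STAT3 list and for the senescence list (exact permutation p = 0.0571 and 0.257).

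**Figure D3:**
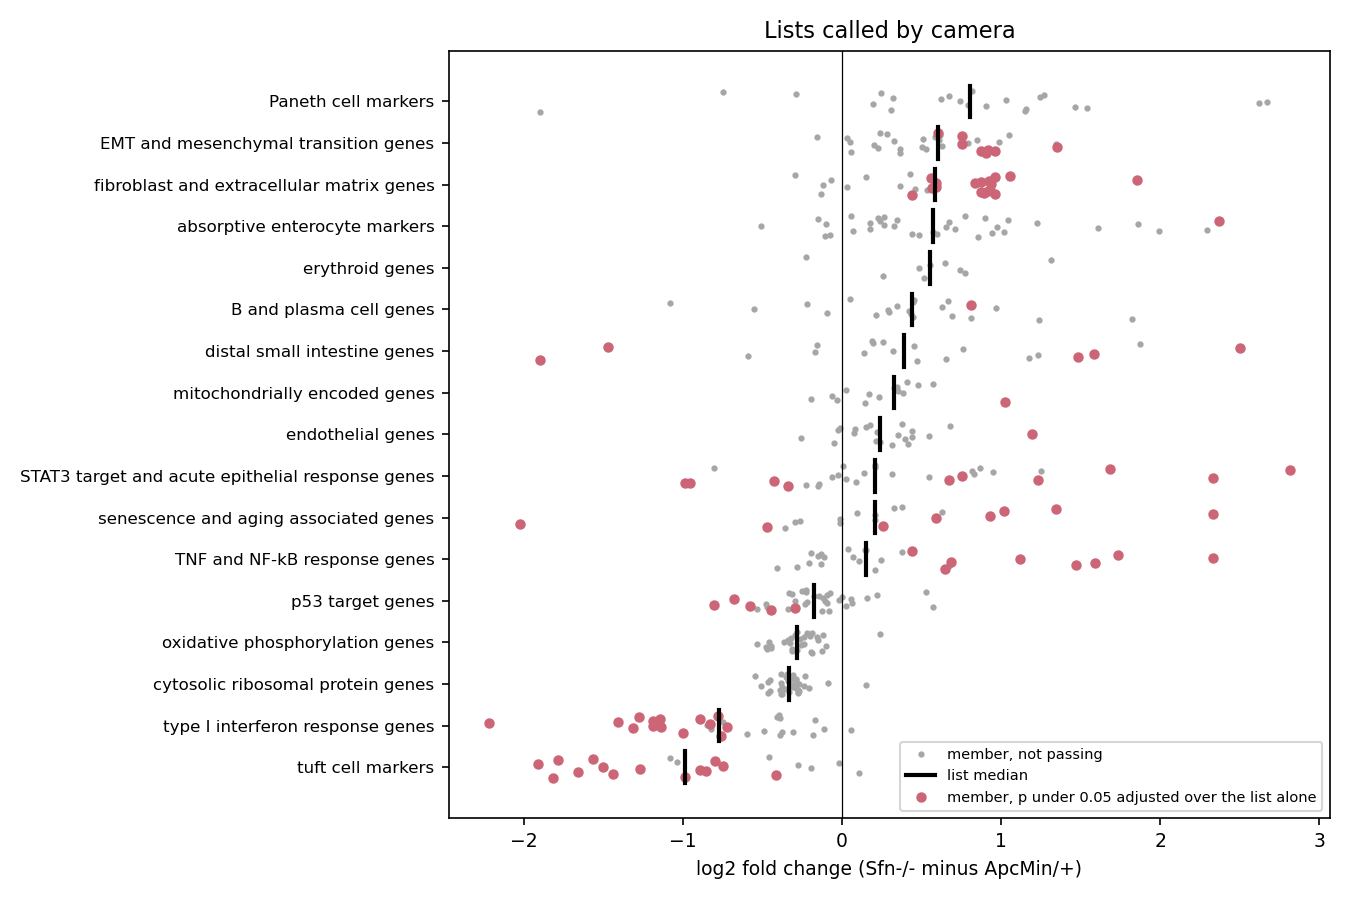
Log2 fold changes of the members of the 17 lists that limma camera called, with red points for genes that passed limma adjusted over the list alone and bars for medians. Tuft cell markers and type I interferon response genes lie mostly below 0, and fibroblast and mesenchymal genes mostly above.

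Other lists were called by limma camera with few or no single genes behind them. Of 35 absorptive enterocyte markers, the disaccharidase gene Sis rose (log2 fold change 2.37, adjusted over the list alone 0.0173), 34 did not pass, and the median was 0.57 (limma camera adjusted p = 1.04e-05; 0.81 with an estimated correlation). Enpep, Lct and Mme had log2 fold changes of 1.61, 1.86 and 1.23. The mean of this list was 11.82 and 12.02 in ApcMin/+ replicates 2 and 3, the libraries with high Xist, against 13.7 in ApcMin/+ replicates 1 and 4 and 13.2 to 13.7 in the knockout libraries. Among the 5 libraries with low Xist the median was -0.24. Paneth cell markers had a median of 0.80 with 0 of 22 passing adjusted over the list alone (limma camera adjusted p = 0.00179; 0.81 with an estimated correlation). Lyz1, Mmp7, Defa17 and Defa3 had log2 fold changes of 1.25, 0.67, 1.16 and 2.62. Values of Defa17 and Defa3 overlapped between the genotypes. Among the 22 markers, 19 lay above 0 and 3 below, with Ang4 at -1.90 (limma, adjusted over the list alone, 0.0659). The Paneth call was lost without ApcMin/+ replicate 4 (median 0.37, adjusted p = 0.143) and without knockout replicate 2 (0.60, adjusted p = 0.0656). Of 20 distal small intestine genes, 3 rose and 2 fell adjusted over the list alone and 0 passed over all genes (median 0.39, limma camera adjusted p = 0.0111; 0.74 with an estimated correlation). Cubn, Osr2 and Guca2a rose by 1.48, 2.50 and 1.58, and Slc34a2 had a log2 fold change of 1.87. Without ApcMin/+ replicate 2 this call of distal small intestine genes was lost (0.23, adjusted p = 0.0939), as it was in the 5 libraries with low Xist (0.21, adjusted p = 0.162).

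Of 22 B and plasma cell genes, Pou2af1 rose by 0.81 (adjusted over the list alone 0.0206) and 21 did not pass, with Jchain, Iglc2 and Blk at 0.63, 0.97 and 1.82 (median 0.44, limma camera adjusted p = 0.00137; 0.81 with an estimated correlation). That call of B and plasma cell genes was lost without knockout replicate 2 (0.28, adjusted p = 0.0755) and in the 5 libraries with low Xist (0.15, adjusted p = 0.101). The 9 erythroid genes had a median of 0.55 with 0 passing, Hba-a1, Hbb-bt, Alas2 and Slc4a1 at 0.74, 0.65, 0.51 and 1.31 (limma camera adjusted p = 0.0316; 0.81 with an estimated correlation). The erythroid call was lost with a filter of 50 (adjusted p = 0.0532), median-ratio scaling (0.0818), quantile normalisation (0.0743) and array weights (0.239), within the shared sequencing order (adjusted p = 0.0515), without ApcMin/+ replicates 1 and 4 (0.119 and 0.195) and without knockout replicates 2 and 3 (0.215 and 0.0611). Of 15 mitochondrially encoded genes, mt-Atp8 rose by 1.03 and 14 did not pass, mt-Rnr1, mt-Rnr2 and mt-Nd6 at 0.57, 0.41 and 0.48 (median 0.33, limma camera adjusted p = 0.0036; 0.81 with an estimated correlation). This call was lost without ApcMin/+ replicate 2 (0.21, adjusted p = 0.0930), and in the 5 libraries with low Xist the median of mitochondrially encoded genes was -0.0397. The 31 nuclear genes of oxidative phosphorylation had a median of -0.28 (limma camera adjusted p = 0.00111; 0.88 with an estimated correlation). Ndufa1, Ndufb10, Cox6c and Cox4i1 had values of -0.53, -0.46, -0.48 and -0.47. The mean of the oxidative phosphorylation list was 13.2 and 13.3 in ApcMin/+ replicates 1 and 4. It was 12.7 in ApcMin/+ replicates 2 and 3 and 12.6 to 12.8 in the knockout libraries. The fall of this list therefore rested on ApcMin/+ replicates 1 and 4, the ApcMin/+ libraries with low Xist. Its median was -0.57 in the 5 libraries with low Xist and -0.37 with Xist-high libraries as a covariate. The 40 cytosolic ribosomal protein genes had a median of -0.33 (limma camera adjusted p = 2.82e-08; 0.81 with an estimated correlation), with Rpl10a, Rpl27, Rps15 and Rpl22 at -0.37, -0.39, -0.45 and -0.45. In both lists 0 members passed adjusted over the list alone, and 30 of 31 and 39 of 40 members lay below 0.

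In all, 17 of 50 lists were called, 12 higher and 5 lower. With an estimated correlation 0 were called (lowest limma camera adjusted p = 0.66; 1 list at an unadjusted p under 0.05), and limma fry called 3 in a common direction. An exact permutation of list means reached p = 0.0286 for 9 lists and 0 after adjustment over the 50. The 14-3-3 family list, which holds the deleted gene Sfn, was 1 of the 3 and 1 of the 9. The knockout itself fixes that outcome. The permutations also assume exchangeable libraries, which these are not, so their p-values can be too small. The 31 Wnt/beta-catenin target genes had a median of -0.0022 and a mean of 0.013, the direction camera tested (limma camera adjusted p = 0.70), with Ascl2 at -0.68 and Myc at -0.51, neither of which passed adjusted over the list alone. They were called higher in the 5 libraries with low Xist (0.39, adjusted p = 4.34e-07), while the other settings gave an adjusted p of 0.0770 or above. The 32 mitosis genes had a median of 0.05, Mad2l1 and Bub1 at 0.34 and 0.36 (limma camera adjusted p = 0.15), and were called without ApcMin/+ replicate 4 (0.18, adjusted p = 0.000195), within the shared order (0.09, adjusted p = 0.0289) and after quantile normalisation (0.12, adjusted p = 0.0259). The 35 MYC target and ribosome biogenesis genes had a median of -0.023 with Fbl and Hspe1 at -0.47 and -0.39 (limma camera adjusted p = 0.99, direction up). Of 27 intestinal stem cell genes, 2 rose, Olfm4 by 1.44 and Aqp4 from a mean of 63.8 to 206.5, and 1 fell adjusted over the list alone (median 0.05, limma camera adjusted p = 0.16). The gene that fell was Ascl2, with a limma p of 0.0343 adjusted over the stem cell list alone. That list was called without ApcMin/+ replicate 2 (0.11, adjusted p = 0.0366) and in the 5 libraries with low Xist (0.26, adjusted p = 0.00103).

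Of 20 fetal and regenerative epithelium genes, Ereg and Ctgf rose over all genes tested, the latter by 0.82, and 1 fell adjusted over the list alone. Ctgf lost its call in 12 of 21 alternative settings. Their median of -0.11 and mean of -0.011 had the opposite sign to the camera direction (limma camera adjusted p = 0.82). Of 25 squamous and stratified epithelium genes, 4 fell adjusted over the list alone, Krt4 and Krt14 among them, the latter by 1.64 (median -0.23, limma camera adjusted p = 0.13). The squamous and stratified epithelium genes were called without a filter (adjusted p = 0.0264) and without knockout replicate 4 (-0.29, adjusted p = 0.0427). Of 25 enteroendocrine markers, 3 fell adjusted over the list alone, including Cpe by 0.78 and the peptide hormone gene Pyy by 1.47 (median -0.22, limma camera adjusted p = 0.57). Over all genes, Cpe lost its call in 13 of the 21 settings. Of 23 Hedgehog and BMP pathway genes, Grem1 rose, and Ihh, at -0.67, did not pass adjusted over the list alone (median 0.11, limma camera adjusted p = 0.22). The Hedgehog and BMP pathway genes were called in the 5 libraries with low Xist (0.27, adjusted p = 0.0156).

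**Figure D4:**
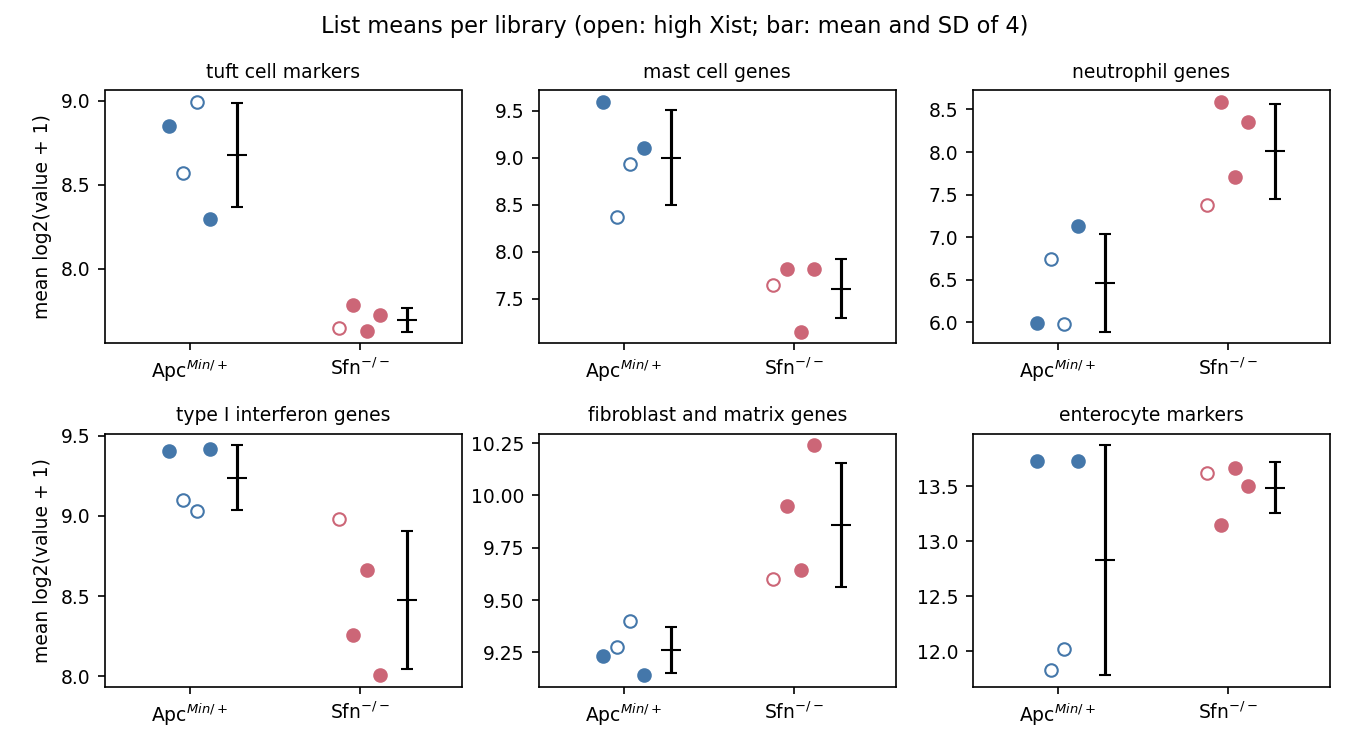
Mean log2(value + 1) of 4 gene lists and of the mast cell and neutrophil members of a further list, per library, with ApcMin/+ in blue, ApcMin/+ Sfn-/- in red, open symbols for Xist above 1000 and bars for the mean and SD of 4 libraries. Tuft cell markers lie between 8.30 and 8.99 in ApcMin/+ and between 7.63 and 7.78 in knockout adenomas, and the 2 open ApcMin/+ points are the lowest for enterocyte markers.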

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

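Among 246 sets of 4 values, each a named gene in a genotype, 4 had a library far from the other 3. Chance gives about 12.3 for independent libraries. The normalisation tied the ApcMin/+ libraries to each other, so this number does not hold for their sets. Hspe1, a mitochondrial chaperone gene, was at 4443 in knockout replicate 2 and between 3292 and 3400 in the other knockout libraries. Cubn, the receptor gene for vitamin B12 bound to intrinsic factor, was at 154 in ApcMin/+ replicate 4 and between 212 and 226 in the other ApcMin/+ libraries. The pseudogene Gm4742 was at 3 in knockout replicate 2 and at 2 in the other knockout libraries, all near the floor. The pseudogene Gm5586 was at 34 in knockout replicate 4 and at 23 or 24 in the other knockout libraries.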

How the results depend on the processing

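The Xist settings, the 0.1 threshold, fry and the test without Sfn were chosen after the data were seen. The number of genes changed was 426 (176 over 2-fold) without the removed direction, 18 (18) with sequencing order as a covariate, 16 (16) in the 6 libraries of the shared order, 13 (13) with array weights, 2194 (676) in the 5 Xist-low libraries and 170 at an adjusted p of 0.1. Leaving out 1 library gave 21 to 346 genes, and 21 to 198 over 2-fold. The cause was not tested. The other settings gave 40 to 60 genes, and in each setting the 58 genes that were tested kept their direction. The targeted gene was -12.76 in the 6 libraries (exact permutation p = 0.0667) and -13.56 in the 5 Xist-low libraries (p = 0.1), the smallest p so few libraries allow, and passed elsewhere. The odds ratio near Sfn kept its direction and its side of the threshold in every setting run, from 1.43 in the 5 Xist-low libraries to 27.6 with sequencing order as a covariate. Camera called 16 to 21 lists in all settings, except 0 with estimated correlation and 3 with fry. Signs turned for lists and genes that were near 0 or rested on few libraries, and the cause was not tested. Without a filter the median was 0.0058 for Wnt targets and 0.38 for neutrophil and mast cell genes. With median-ratio scaling Ywhaz was at 0.0328, Wnt/beta-catenin target genes at 0.0592 and MYC targets and ribosome biogenesis genes at 0.0385. With quantile normalisation Ywhag was at 0.0129, Ywhaz at 0.0819, Wnt targets at 0.0447 and MYC targets at 0.0408. MYC targets were at 0.0015 with sequencing order as a covariate and in the 6 libraries. With Xist-high libraries as a covariate Wnt targets were at 0.10. With array weights Hdc was at -0.22. In the 5 Xist-low libraries Kit was at 0.19, Ywhag at 0.0164, Mme at -0.0548, enterocyte markers at -0.24, mitochondrially encoded genes at -0.0397, Wnt targets at 0.39, mitosis genes at -0.0663 and neutrophil and mast cell genes at 0.0370. Over the libraries left out, Hdc ranged from -0.11 to 0.46, Ywhag from -0.14 to 0.000701, Ywhaz from -0.0844 to 0.0392, Wnt targets from -0.0917 to 0.14, stem cell genes from -0.0472 to 0.11, mitosis genes from -0.0786 to 0.18, MYC targets from -0.11 to 0.0881 and Hedgehog and BMP genes from -0.0078 to 0.18. Of 693 values of the 33 named genes that passed, 513 kept their call, 180 lost it and 0 turned. No paired analysis was possible because the labels give mouse numbers that differ between the genotypes. Depth is unknown, and 4 mice per genotype of non-overlapping ages limit what the comparison can assign to genotype.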

Other observations

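Mast cell genes were lower and neutrophil genes higher in the knockout adenomas. A preset list of both cell types did not pass limma camera (adjusted p = 0.83, median -0.31, mean 0.011), but 8 of its 23 measured members rose and 11 fell adjusted over the list alone, and 0 passed over all genes. Of the 12 mast cell genes, 10 fell and 0 rose, with a median log2 fold change of -1.66. The mast cell protease gene Mcpt1 went from 10723 ± 6375 to 2159 ± 635 (SD, n = 4 each), a log2 fold change of -2.14 (limma adjusted p over all genes 0.102). The tryptase gene Tpsab1 fell by 1.69, the carboxypeptidase gene Cpa3 by 1.48 and Ms4a2, a subunit of the high-affinity IgE receptor, by 1.88, while Hdc (0.17) and Kit (-0.31) did not pass. Of the 11 neutrophil genes, 8 rose and 1 fell, with a median of 1.68. The chemokine receptor gene Cxcr2 rose by 1.68, S100a9 by 1.68 and Retnlg by 2.35, and the granule protein gene Ltf fell by 0.47. The library means of the mast cell genes lay between 8.36 and 9.59 in ApcMin/+ and between 7.15 and 7.81 in knockout adenomas, and those of the neutrophil genes between 5.98 and 7.13 and between 7.38 and 8.59 (exact permutation p = 0.0286 for each). After the normalisation the libraries are not exchangeable, so this permutation p can be too small.

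The mast cell and neutrophil split, the gene and pseudogene tests, the tests of the Sfn region on chromosome 4 other than the window itself and sequencing order, and the splits of the libraries for single genes and for the window were chosen after the result was seen. The tests of sequencing order and sex and the splits for lists had their predictions written before they were run.

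Within the shared sequencing order the median was -1.66 for the mast cell genes and 1.73 for the neutrophil genes. The normalisation had removed the contrast between orders, which fixes this outcome, so an effect of sequencing order stays open. Sex of the mice is argued against, since with the Xist-high libraries as a covariate the medians were -1.70 and 1.56. Age remains open: the oldest knockout mouse was 108 days younger than the youngest ApcMin/+ mouse, so a change of these cells with age or with the time a tumour has grown cannot be told apart from an effect of 14-3-3σ loss. A hypothesis consistent with the 2 medians is that knockout adenomas held fewer mast cells and more neutrophils, and cell numbers were not measured. A lower share of epithelium would raise the genes of both cell types, which moved apart.

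The excess of changed genes around Sfn may come from DNA of another mouse strain carried along with the targeted allele. With Sfn left out, the odds ratio within 10 Mb was 9.28. An effect of 14-3-3σ loss that reaches genes anywhere in the genome alike would put it near 1, and its lower 95% bound was 3.76. An effect of the targeted allele on its close neighbours alone is argued against by genes 2 to 20 Mb away, of which 8 of 439 passed (odds ratio 7.05, 95% interval 2.85 to 15.3). On the same chromosome, 0 of 177 genes 20 to 40 Mb from Sfn and 4 of 356 genes beyond 40 Mb (1.12%) passed. The latter share was above the 0.283% of all genes outside the 10 Mb window. All 8 genes near Sfn kept their direction and most of their change within the shared sequencing order, an outcome that the normalisation fixes here too, so an effect of sequencing order stays open. The labels give a C57BL/6 background and no sequence was analysed here, so a strain difference remains a hypothesis. The excess of 10 genes on chromosome 3 included Rps3a1 and Cd1d2. Cd1d2, annotated as a polymorphic pseudogene (86986551 on that chromosome), rose by 3.15 and lost its call in 7 of 21 settings. Whether DNA of another strain accounts for the excess on chromosome 3 was not tested.

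Reads of a gene assigned to a pseudogene copy could account for part of the changes of Rps3a1, Hdac1 and Ndufs5, and the tables leave this open. The best-matching coding gene moved against its pseudogene, with p under 0.05, for 4 of 11 changed pseudogenes and for 45 of 722 others (odds ratio 8.54, 95% interval 1.77 to 35.1; Fisher's exact p = 0.00412). No minimum of shared words was set, and Hyi, among the 11 changed pseudogenes, shared only 0.0443% of its words with its match Mocs2. The 4 pairs prompted this test of opposite movement and Psma3 with Gm4742 is one of them, so it restates what was seen. Over all such pairs, lower transcription of the coding gene is open as well: of 4 changed pseudogenes whose coding gene fell, 3 rose and Gm5586, matched to Rps3a1, fell by 2.20. For Rps3a1 the copies moved apart. The rise of Rps3a3 by 8.51 argues against lower transcription as the only cause, while the fall of Gm5586 goes with it. For Hdac1 and Ndufs5 lower transcription is argued against as the only cause, since their copies Gm10093 and BC002163 rose by 7.96 and 7.42 on the log2 scale. The copies Rps3a3, Gm10093 and BC002163 gained 53%, 62.7% and 49.4% of what Rps3a1, Hdac1 and Ndufs5 lost, so part of each fall stays open. For Psma3 the exchange is argued against, since Gm4742 lost only 4.59% of what Psma3 gained. A strain variant in the coding gene that matches the copy in the reference is a candidate cause for Hdac1 and Ndufs5, which lie within 10 Mb of Sfn, and was not tested.

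Chance as the source of the gene counts was examined with all 35 splits of the 8 libraries into 4 and 4. The real split gave 58 genes and 48 over 2-fold, no other split gave more than 1, and 1 of 35 splits, the real one, was as large. For genes within 10 Mb of Sfn the real split gave 9 and the highest other split 0, 1 of 35 as large. The normalisation removed differences between replicates of a genotype, which favours the real split, so these 3 counts do not settle whether chance can be excluded. For gene lists called by camera chance cannot be excluded, since 23 of 35 splits gave as many as the 17 lists of the real split, and the highest other split gave 29.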
